A study of Macrobrachium rosenbergii with 9 samples.

How the data were processed

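RNA was measured in 9 libraries of adult Macrobrachium rosenbergii, 3 each of testis, androgenic gland and ovary, as given by the sample titles. Per the labels' protocols, prawns were anaesthetised on ice, the tissues were dissected, rinsed in buffered saline and frozen, RNA was purified with a column kit, and libraries were made with a directional (strand-keeping) Illumina kit. The authors deposited 1 table of estimated counts per transcript, whose columns the file headers call read counts, beside a transcript length in bases. Between 46.87% and 64.34% of the values of a library were whole numbers, zeros included, and the rest had decimals. These are therefore expected counts, in which a read can be shared out between transcripts. Per the submitters' processing notes the tools were Bowtie 0.12.2 and DESeq 1.10.1 and a build was named mm8, which is a mouse build. The notes give no roles, and the counting tool, the strand setting and the source of the transcripts are not given in the sources used here. The transcript IDs carry the words HQ (20827 transcripts) or LQ (244), Female or Male, and a length that equals the deposited length in 13906 of 21071 transcripts. Deposited lengths ran from 155 to 7713 bases with a median of 1511. No ID matched the 31758 genes of the reference table, so the 18 gene lists fixed before the data were examined could not be tested.

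Expected counts were rounded to whole numbers for the tests. Transcripts with enough counts were kept with edgeR's filterByExpr at its defaults, a minimum count of 10 and a minimum total of 15, with the tissues as groups. This left 17043 transcripts holding 97.24% to 99.92% of each library's counts, while 442 had no count in any library and 3586 had too few. Libraries were scaled by TMM factors, which were 1.265, 1.277 and 1.555 in testis, 0.5253, 0.3798 and 0.5748 in androgenic gland, and 1.58, 1.479 and 1.485 in ovary. These factors differ several-fold between tissues, and with them a change is read relative to the bulk of transcripts and not to the total. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) in 1 fit of all 9 libraries with a mean per tissue, 6 residual degrees of freedom and a prior count of 1. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, two-sided. A transcript was put in a tissue's set when it was called in the same direction against both other tissues. Groups of transcripts by sex label, length and LQ were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, from limma 3.58.1. These were 15 tests in all, with adjusted p-values over the 15. Every transcript carries either the female or the male label, so each label group was compared with the other. At the preset correlation their camera results are therefore 1 test counted for both groups. The fry test asks whether a group moves 1 way on balance and compares it with no other transcripts. Figures were drawn with matplotlib from the tabulated values.

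The rule for transcripts named in the text was fixed before the data were examined. With no names in the files, it took at most 2 IDs that rose and 2 that fell per comparison, those with the largest change among called transcripts whose values did not overlap between tissues and whose mean in the higher tissue was at or above the median of tested transcripts, 9.43 CPM. CPM values in the text are scaled to the library size multiplied by its TMM factor. A fitted log2 fold change against a tissue with few or 0 counts depends on the prior count and is not a bound. The value after ± beside it is the size of the log2 fold change over the square root of the F statistic. That value is a rough SE, since edgeR's F test gives none. A ratio against a tissue with counts uses the tissue totals and an exact Poisson interval at 95%, and a ratio against a tissue with 0 counts uses a floor of 3 counts over the tissue. These intervals and floors cover counting error only. The same floor of 3 counts in a single library is between 0.181 CPM in ovary 2 and 0.759 CPM in androgenic gland 2. It is the level that a count of 0 allows, and values below it can still rest on 1 or 2 counts.

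Libraries of testis and androgenic gland with the same number deviated together from their tissue means, with correlations across 17043 transcripts of 0.29 to 0.42, against at most -0.016 between other numbers, which the centring on tissue means pulls below 0. The numbers were therefore taken to pair these tissues, but only in alternative fits and in part of the splits. Those fits had a term per number, the replicate block. This pairing comes from the data and not from the labels. The main fit had no block, so its results and the permutation tests for androgenic gland versus testis are unpaired. Same-numbered libraries of testis and ovary reached -0.14 to 0.0086 and those of androgenic gland and ovary -0.14 to 0.003, so these were not treated as paired. No libraries were near-identical copies.

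The steps were tested on simulated counts with the observed means, dispersions and library sizes, with 200 transcripts changed in ovary. For ovary versus testis, with 16533 transcripts tested, 0 of 67 changed by 2-fold, 3 of 67 by 4-fold and 43 of 66 by 16-fold were called, with 3 false calls. The medians of the estimated log2 fold changes were 0.90, 1.96 and 3.88 where 1, 2 and 4 had been simulated. For androgenic gland versus ovary the calls were 0 of 67, 5 of 67 and 42 of 66, with 4 false calls. Small changes were therefore hard to call when few transcripts changed. Alternatives fixed before the data were examined were size factors of DESeq2 1.42.0, other filters, prior counts of 0.1 and 5, DESeq2, limma-voom, robust edgeR, adjusted p alone, a log2 threshold of 2, only the 6 libraries compared, the replicate block and leaving out each library. Library-size scaling without TMM factors, the 6 libraries with the block, and the label and length groups were added after seeing the data. Alternatives for normalized values and for 1 ID per gene name did not apply.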

Results

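Transcript abundance was compared between testis, androgenic gland and ovary of adult Macrobrachium rosenbergii, the giant freshwater prawn, in 9 RNA-seq libraries of the strain labelled CMr1. The androgenic gland is a male-specific endocrine organ of decapod crustaceans that lies along the sperm duct and secretes the hormone driving male differentiation. Each tissue had 3 libraries. The study's title places them in a search for transcription factors tied to sex determination. Total counts were 8823483, 9868078 and 7142794 in testis 1 to 3, 11177153, 10409895 and 11119429 in androgenic gland 1 to 3, and 9924471, 11231573 and 10150760 in ovary 1 to 3. The table held 21071 transcripts, of which 14774 carried the word Female and 6297 the word Male in their ID, and 17043 had enough counts to be tested. The files do not pair the IDs with gene names, and 0 of the IDs matched the 31758 reference genes, so transcripts are described by ID, sex label, length and tissue pattern. Several transcripts can belong to 1 gene and share its reads, so counts below are of transcripts, not of genes. The labels do not say that the libraries of a tissue came from separate animals, so p-values measure the spread between these libraries only.

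The androgenic gland spent most of its reads on few transcripts, and the ovary spread them over many. The 10 most abundant transcripts took 36.71% ± 5.93 of counts in androgenic gland, 18.1% ± 4.87 in testis and 8.191% ± 0.727 in ovary (SD, n = 3 each). It took 27 ± 10.6 transcripts to reach 50% of the counts in androgenic gland, 227.3 ± 70.6 in testis and 555.7 ± 22 in ovary. At least some count was present for 14320 ± 390 transcripts in androgenic gland, 17040 ± 205 in testis and 18540 ± 95.7 in ovary. The tissues differed in this by sex label. After removal of dominant transcripts and thinning to 1 total, 4724 ± 137 male label transcripts were detected in androgenic gland, 5273.3 ± 133 in testis and 4614.3 ± 88.5 in ovary (SD, n = 3 each). For female label transcripts the numbers were 8976.7 ± 150, 10760 ± 235 and 12735 ± 47.5. For the share of the top 10, the transcripts that reach 50% and the transcripts with a count, the tissues did not overlap, and the two-sided exact permutation p was 0.1 in each pair of tissues, the smallest that 3 against 3 libraries can give. A transcript of 482 bases with the female label, singled out after the values were seen, took 11.3%, 10.4% and 6.26% of the counts in androgenic gland 1 to 3. The same transcript took 1.32%, 5.45% and 2.3% in testis 1 to 3 and 0.0667% in ovary 1, where it was highest among the ovary libraries. The 95% Wilson interval of any share of counts in a single library given here reaches at most 0.0367 percentage points to either side, which covers counting error only.

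Tissue set the main axes of variation between libraries. The first principal component held 63.6% of the variance and parted ovary from both male tissues, and the second held 21.5% and parted testis from androgenic gland. Correlations across transcripts of log2 CPM within a tissue lay between 0.901 and 0.935, except for testis 2, which reached 0.824 with testis 1 and 0.854 with testis 3. Transcripts are not independent replicates, so these values only describe the libraries. The third component held 5.83% of the variance and placed testis 2 and androgenic gland 2 on 1 side, apart from the other male libraries.

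**Figure D1:**
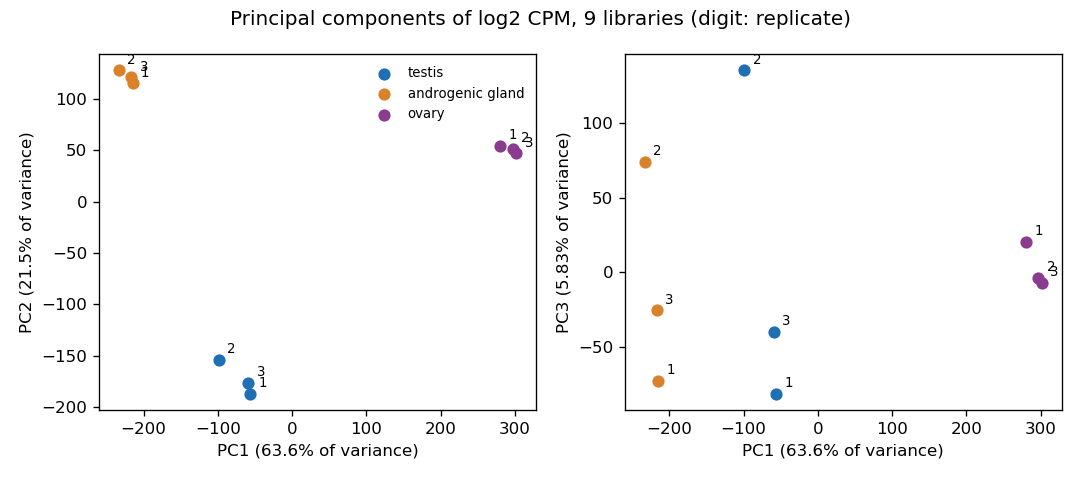
The 9 libraries on principal component 1 against component 2 (left) and component 3 (right), with the share of variance on each axis; each point is a library, coloured by tissue and marked with its replicate number. The 3 tissues lie apart on the first 2 components, and testis 2 lies at 135.7 on component 3, against -81.56 and -39.72 for testis 1 and 3.

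Ovary and testis, the gonads of the 2 sexes, differed in a large part of the transcripts tested. In ovary 4524 transcripts were higher and 3335 lower than in testis, 46.1% of the 17043 tested. The ovary-higher transcripts were changed more strongly, with a median log2 fold change of 3.91 against -2.16 for the testis-higher ones. Of the ovary-higher transcripts, 1079 had no count in any testis library. With such transcripts set to their bound of 3 counts over the tissue, the medians were 3.90 and -2.16, and 1744 transcripts were at least 32-fold higher in ovary against 519 lower. Among 11847 tested transcripts with the female label 4050 rose and 1602 fell in ovary relative to testis, and among 5196 with the male label 474 rose and 1733 fell. The female label group ranked higher in ovary than the male label group (camera, adjusted p = 2.8e-13). With the correlation estimated in the female or the male label group the camera adjusted p was 0.002 or 0.0036.

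Among single transcripts, transcript_HQ_Female_transcript10749/f2p0/1681 averaged 3820 ± 447 TMM-scaled CPM in ovary (SD, n = 3) and had 1.32 estimated counts over the 3 testis libraries. Its log2 fold change was 14.94 with a rough SE of 1.33 from the F statistic (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00015). Its ratio of 99500 had a 95% counting interval of 23600 to 5190000. For transcript_HQ_Female_transcript16105/f34p0/1271 the ovary mean was 6190 ± 1390 CPM and the log2 fold change 14.54 ± 1.19 (edgeR, adjusted p = 0.00012). In the other direction, transcript_HQ_Male_transcript4043/f8p0/1868 stood at 11000 CPM in testis 1 and 7740 in testis 3 but 14.1 in testis 2, with 3 counts over the ovary libraries. Its log2 fold change was -15.28 ± 2.9 (edgeR, adjusted p = 0.003), and its ratio of 98300 had a counting interval of 33600 to 477000. Testis 2 also stood apart for transcript_HQ_Male_transcript8133/f2p0/1233, at 32.9 CPM against 14400 in testis 1 and 7150 in testis 3, with a log2 fold change of -15.16 ± 2.39 (edgeR, adjusted p = 0.0013). Without testis 2 the count was 4423 higher and 3072 lower in ovary, of which 4036 and 2768 were the same transcripts.

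The androgenic gland was compared with testis, the other male organ sampled. In androgenic gland 2730 transcripts were higher and 4581 lower than in testis, 42.9% of those tested. The transcripts lower in androgenic gland had a median log2 fold change of -2.92 against 1.98 for the higher ones, and of these lower transcripts 1090 had no count in any androgenic gland library. With such transcripts at their bound the medians were -2.73 and 1.98. The sex label groups were not called against each other (camera, adjusted p = 0.84), while each moved down on balance (fry, adjusted p = 0.00011 and 0.00022). Among transcripts with the female label 1614 rose and 2976 fell in androgenic gland, and among those with the male label 1116 rose and 1605 fell. The size of this imbalance depended on the scaling. Scaling to library size without TMM factors gave 565 higher and 8526 lower, so the share of calls that were higher was 6.21% in place of 37.3%, and the median log2 fold change of all transcripts went from -0.28 to -1.5.

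Of the transcripts highest in androgenic gland against testis, transcript_HQ_Male_transcript7580/f6p0/1294 stood at 1870, 1740 and 3620 CPM in androgenic gland 1 to 3 and at 0.455 CPM or less in each testis library (log2 fold change 12.72 ± 1.2; edgeR, adjusted p = 2e-04). All testis libraries had 0 counts of transcript_HQ_Male_transcript3900/f4p0/1903, which was at least 7090-fold higher in androgenic gland against the floor of 3 counts over the tissue. That value rested on androgenic gland 2, at 1780 CPM against 50.3 and 29.6 in the other two, and the log2 fold change of 12.71 (edgeR, adjusted p = 0.021) was 8.82 without it. Among the transcripts lower in androgenic gland, transcript_HQ_Male_transcript4331/f2p0/1809 had 0 counts in all 3 of its libraries and was at least 5390-fold lower, with 1730, 8.96 and 1260 CPM in testis 1 to 3 (edgeR, adjusted p = 0.0053). For transcript_HQ_Male_transcript4814/f3p0/1733 testis 1 to 3 had 5920, 5.76 and 2600 CPM and the androgenic gland 1 count in all, a ratio of 46000 with a counting interval of 8260 to 1820000. Its log2 fold change of -14.13 ± 2.87 (edgeR, adjusted p = 0.0078) was -15.03 with an adjusted p of 0.055 without androgenic gland 2. Leaving out testis 2 gave 2624 higher and 4551 lower transcripts, 2300 and 4133 of them the same.

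By number of calls, the androgenic gland differed from the ovary more than the other pairs of tissues did. This rested on female label transcripts, of which 4423 were not called, against 6195 for ovary versus testis and 7257 for androgenic gland versus testis. Of the male label transcripts 2482 were not called, about as many as the 2475 for androgenic gland versus testis. In androgenic gland 3428 transcripts were higher and 6710 lower than in ovary, 59.5% of those tested. The ovary-higher transcripts had a median log2 fold change of -4.27, or -3.76 with the 2679 transcripts that had no count in androgenic gland at their bound, against 2.25 for the androgenic gland-higher ones. The female label group ranked lower in androgenic gland than the male label group (camera, adjusted p = 3.2e-08). With the correlation estimated in the female or the male label group the camera adjusted p was 0.002 or 0.0039. In the female label group 1894 transcripts were higher and 5530 lower, and in the male label group 1534 were higher and 1180 lower. The ranking holds only for 1 label group relative to the other. Under scaling to library size 718 transcripts of the male label group were higher and 2430 lower in androgenic gland, so the balance of its calls turned around. That scaling gave 1152 higher and 10635 lower among all transcripts, a higher share of 9.77% in place of 33.8%, with the median log2 fold change at -2.2 in place of -0.65.

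Under the naming rule the largest log2 fold change over ovary was 17.51 ± 1.77 (edgeR, adjusted p = 0.00012), for transcript_HQ_Male_transcript11417/f4p0/681. It had 30700, 35800 and 21800 CPM in androgenic gland 1 to 3 and 3.45 estimated counts over the ovary libraries. Its ratio of 403000 had a counting interval of 158000 to 2250000. It was also present in testis, at 987, 5010 and 1000 CPM in testis 1 to 3. For transcript_HQ_Male_transcript7617/f2p0/1307 the androgenic gland libraries had 28000, 58600 and 27500 CPM and the testis libraries 612, 10200 and 742 CPM, with a log2 fold change to ovary of 17.13 ± 2.33 (edgeR, adjusted p = 0.00042). From ovary, transcript_HQ_Female_transcript3822/f2p0/2405 had 1300 ± 177 CPM (SD, n = 3) and 0 counts in every androgenic gland and testis library, and was at least 7000-fold lower in androgenic gland (edgeR, adjusted p = 0.00012). Likewise transcript_HQ_Female_transcript19513/f2p0/1126 had 1070 ± 495 CPM in ovary and 0 counts in all male libraries, at least 5760-fold lower in androgenic gland (edgeR, adjusted p = 0.00041).

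Each tissue had its own set of transcripts higher than in both others, and the ovary's was the largest. Its lead rested on female label transcripts, at 3518 against 1051 for androgenic gland and 692 for testis. Among male label transcripts the ovary set was the smallest, at 280 against 890 for androgenic gland and 841 for testis. The ovary set held 3798 transcripts, 92.6% of them with the female label against 69.5% of all tested. The androgenic gland set held 1941 transcripts, 54.1% with the female label, and the testis set 1533, 45.1% with the female label. Transcripts lower in 1 tissue than in both others numbered 3123 for androgenic gland, 1488 for ovary and 539 for testis. Scaling to library size without TMM factors gave 4523 transcripts higher in ovary, 1922 in testis and 413 in androgenic gland than in both others, so the order of the male tissues turned around. With it 6937 were lower in androgenic gland, 656 in ovary and 95 in testis than in both others. The androgenic gland set took 48.2% ± 3.26 of the counts in androgenic gland, 16% ± 4.54 in testis and 10.2% ± 0.519 in ovary (SD, n = 3 each). The ovary set took 43% ± 1.25 of the ovary counts, 2.54% ± 0.406 in testis and 0.85% ± 0.215 in androgenic gland. The sets were chosen on these same libraries, so a larger share in a set's own tissue is largely fixed by that choice. The testis set took 42.2% and 32.4% of the counts in testis 1 and 3 but 9.8% in testis 2. Its mean was 28.1% ± 16.6 with testis 2 and 37.3% without it. In testis 2 the androgenic gland set took 20.5%, against 11.5% and 16.1% in testis 1 and 3, and the transcripts lower in ovary than in both male tissues took 43.3% against 13.6% and 17% in testis 1 and 3. Without testis 2 in the fit the testis set held 1459 transcripts, 1266 of them from the set of 1533.

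**Figure D2:**
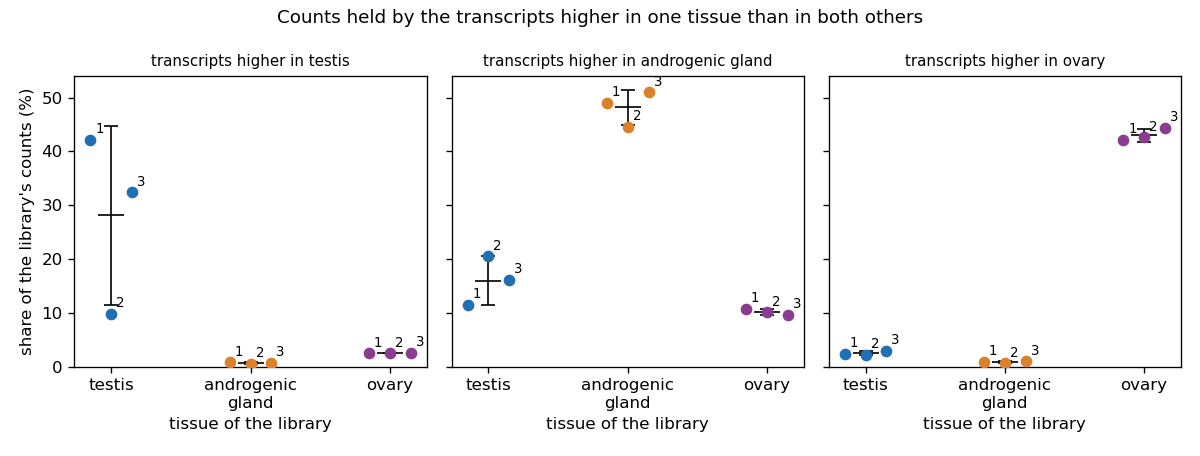
Share of each library's counts, in percent, held by the transcripts higher in testis (left), androgenic gland (middle) or ovary (right) than in both other tissues; points are libraries with their replicate number, and the bars give the mean and SD of 3 libraries. The testis set takes 42.2% and 32.4% of counts in testis 1 and 3 and 9.8% in testis 2. The sets were chosen on these same libraries, which largely fixes a larger share in a set's own tissue.

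Each of these sets joins a pair of comparisons that share the libraries of the tissue. Independent lists of the same sizes would share 1781 transcripts for ovary, 549 for androgenic gland and 896 for testis. In counts simulated with no effect edgeR called 0 transcripts in each comparison, with 733, 713 and 707 of 16452 at an unadjusted p under 0.05, and so put 0 in each set. With no transcript called, that simulation cannot measure how far the shared libraries raise the overlap. Part of the excess over independent lists can come from the shared libraries, which were too few to split.

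**Figure D3:**
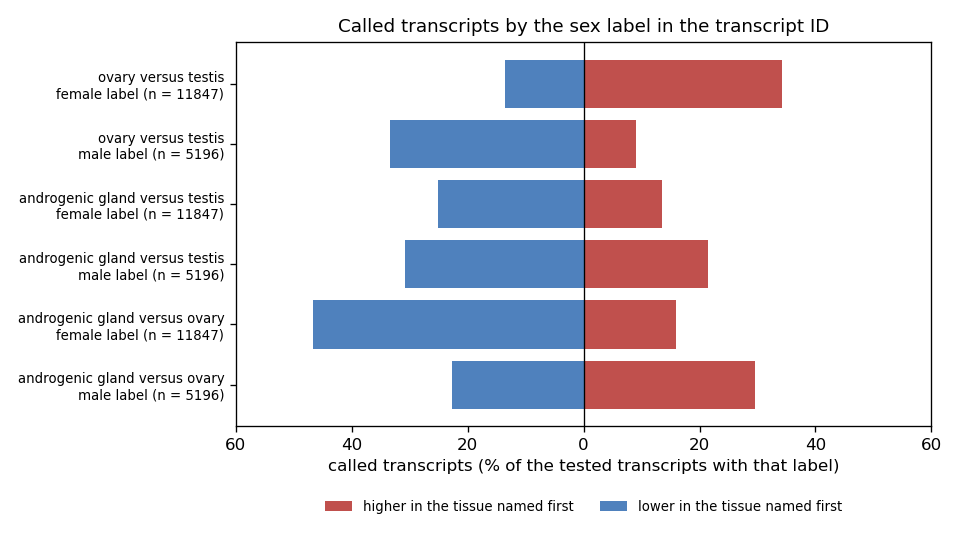
Percent of the tested transcripts with the female or male label in their ID that were called higher (right) or lower (left) in the tissue named first, for each comparison. Female label transcripts are called 34.2% higher and 13.5% lower in ovary against testis, and male label ones 9.12% higher and 33.4% lower; the male label excess of higher calls in androgenic gland against ovary turns around under scaling to library size.

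The sex label followed the tissue in the share of counts as well. Transcripts with the female label took 68.55% ± 0.817 of the counts in ovary, 33.73% ± 3.35 in testis and 26.82% ± 3 in androgenic gland (SD, n = 3 each). The two-sided exact permutation p was 0.1 for each pair of tissues, the smallest possible here. Whether the labels name libraries made from these same tissues is not given in the sources used here, so the label is not independent evidence of direction.

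Transcripts were also grouped by length, after the IDs were seen. Of 3485 tested transcripts under 1000 bases 1502 were higher and 508 lower in ovary against testis (camera, adjusted p = 2.3e-05; adjusted p = 0.073 with an estimated correlation, so this call was lost). Against ovary, 592 of them were higher and 1877 lower in androgenic gland (camera, adjusted p = 0.011; adjusted p = 0.18 with an estimated correlation and 0.14 under scaling to library size, so this call was lost too). That scaling gave 269 higher and 2411 lower. Of 5961 transcripts of 2000 bases or longer 1062 were higher and 1381 lower in ovary against testis (camera, adjusted p = 0.0045; adjusted p = 0.043 with an estimated correlation), but on balance they passed no threshold (fry, adjusted p = 0.13). Under scaling to library size 1150 were higher and 1150 lower, so the excess of lower calls was gone. Against ovary, 1415 of these long transcripts were higher and 1803 lower in androgenic gland, and under scaling to library size 361 and 3468. They ranked above the other transcripts there (camera, adjusted p = 0.02; adjusted p = 0.025 with an estimated correlation but 0.3 under scaling to library size), with a median log2 fold change of -0.10 against -1.01, while on balance they moved down (fry, adjusted p = 9.9e-05). Between androgenic gland and testis neither the short nor the long group was called (camera, adjusted p = 0.54 and 0.84), while each moved down on balance (fry, adjusted p = 0.02 and 7e-05). The short group had 479 higher and 716 lower calls there, but its median log2 fold change was 0 against -0.345 for the other transcripts. The 96 tested transcripts with LQ in their ID were not called in any comparison (camera, adjusted p = 0.84, 0.083 and 0.14), and in ovary against testis their median of -0.18 and the upward balance in fry (adjusted p = 0.0081) differed in sign. Within the female label group 52.5% of the transcripts under 1000 bases and 22.7% of those of 2000 bases or longer were higher in ovary than in testis, and within the male label group these shares were 10.3% and 8.06%. No test was run within the label groups, which were themselves chosen after the IDs were seen.

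A set of 1081 transcripts higher in testis than in both other tissues, drawn up without testis 2, fell into separate parts in that library. In testis 2, 875 of them, or 80.9%, lay within 4-fold of the mean of testis 1 and 3. Another 184, or 17%, were over 16-fold lower, with a median log2 ratio of -8.43. These 184 transcripts took 36.2% of the counts in testis 1, 23.7% in testis 3 and 0.0745% in testis 2, and 96.2% of them carried the male label. In androgenic gland they took at most 0.00472% of counts and in ovary at most 0.00927%.

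**Figure D4:**
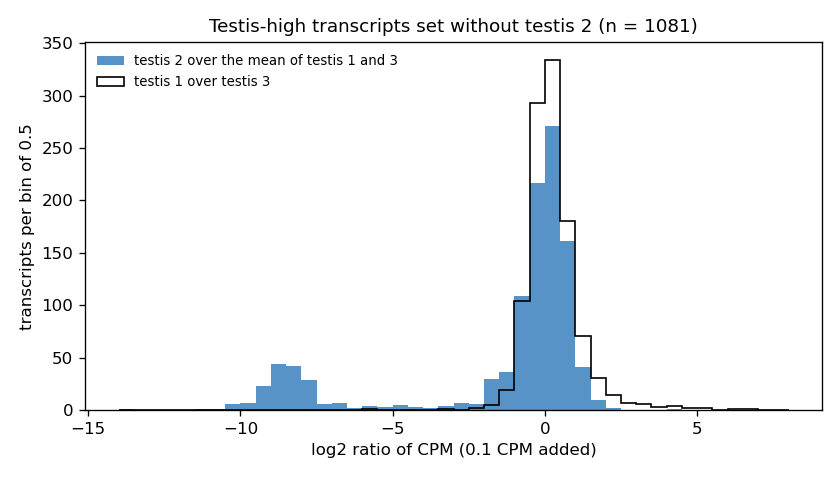
Histogram of the log2 ratio of CPM for 1081 testis-high transcripts, drawn up without testis 2 at a minimum of 10 CPM. Testis 2 over the mean of testis 1 and 3 is in blue, and testis 1 over testis 3 is a black outline. The vertical axis counts transcripts per bin of 0.5. In testis 2 there are 875 transcripts within 4-fold of testis 1 and 3 and 184 that are over 16-fold lower.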

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

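The tests with library-size scaling, the 6-library block, the label and length groups and the splits that keep the pairs were chosen after the data were seen, and the other settings before. Of 333 counts of calls recomputed under other settings 316 stayed within 1.5 times the reported count, 249 of 250 values of named transcripts kept their direction and call, and none of either reversed. Of 210 group tests 193 kept their call, 5 lost it, 11 gained it and 1 reversed. These count both sex label groups, which at the preset correlation are the same camera test. Lost were transcripts under 1000 bases with an estimated correlation in ovary against testis and against androgenic gland, those of 2000 bases or longer in ovary against testis with fry, and both length groups in androgenic gland against ovary under library-size scaling. Reversed was the group of 2000 bases or longer in androgenic gland against ovary, which ranked above the other transcripts but moved down on balance in fry, with a median of -0.102. No test of a sex label group lost its call. Calls were gained with fry (5), library-size scaling (3) and in the LQ group without 1 library (3). Scaling to library size without TMM factors gave 565 transcripts higher and 8526 lower in androgenic gland against testis, 1152 higher and 10635 lower against ovary, and 413 higher and 6937 lower than in both. It left 95 lower in testis and 656 lower in ovary than in both other tissues. The factors it drops are lowest in androgenic gland, which shifts every androgenic gland value down. Requiring a log2 fold change of at least 2, which by construction calls fewer, gave 1847 transcripts lower in ovary than in testis, 4652 called between androgenic gland and testis with 1325 of them higher, and 1990 higher in androgenic gland than in ovary. It left 779 higher in testis, 929 higher in androgenic gland, 154 lower in testis and 670 lower in ovary than in both others. With limma-voom 915 transcripts were lower in testis than in both others, and the cause was not tested. With the replicate block, where the pairing of testis and androgenic gland bears on the test, 2682 transcripts were higher and 4305 lower in androgenic gland against testis, and 2807 and 3979 with the 6 libraries alone. The block changed no call of a named transcript or transcript group, nor any count by over 1.5 times. For ovary, whose numbers did not pair it with the male tissues, the block gave 4460 higher and 3075 lower against testis, and 3315 higher and 6676 lower in androgenic gland against ovary. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real splits, fitted on those libraries alone, called 7847 (ovary, testis), 6492 (androgenic gland, testis) and 9954 (androgenic gland, ovary), and 1 of 10 splits reached each, the real one. The highest other split called 0 by edgeR, with at most 284, 497 and 176 at an unadjusted p under 0.05. For androgenic gland and testis this includes the 3 other splits that part all 3 pairs. Among 60 drawn splits of all 9 libraries 1, the real one, reached its 7272 transcripts higher in 1 group than in both others. The highest other gave 2922. Other splits mix tissues within a group, which widens its spread and lowers the calls. Free splits also ignore the pairing, so they do not exclude chance. Of the 60 drawn splits, 27 part all 3 testis and androgenic gland pairs, and the highest other of these gave 1061. Exchanges within pairs make 4 splits, too few for a share under 0.05, and those other than the real one gave 2802 to 2890.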

Other observations

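All tests on testis 2 and the test on same-numbered libraries coming from the same male were chosen after those results were seen, while the tests on abundant transcripts, on the transcript catalogue and on the reach of the pairing were set before their values were seen. A transcript of 1295 bases, singled out after its values were seen, took between 2.04% and 4.52% of the counts in every library. In testis 2, 325 transcripts stood at 20 CPM or more and at least 8-fold above every other library, and took 6.45% of its counts. The other libraries had between 4 and 23 such transcripts each. Of these 325 transcripts 222 carried the male label, and 269 were highest in androgenic gland 2 among the androgenic gland libraries.

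In testis 2 a block of 184 testis-high transcripts was over 16-fold lower than in testis 1 and 3. A separate set of 1636 androgenic gland-high transcripts, with a minimum of 10 CPM, took 30% of the counts in testis 2. In testis 1 and 3 it took 11.5% and 16.3%. This is not the set of 1941 given above, which took 20.5% in testis 2. The median log2 ratio of the 1636 to testis 1 and 3 was only 0.21 (quartiles -0.28 and 0.82), with 88.9% within 4-fold. Dilution of testis with a tissue without testis-high transcripts would lower all of them by 1 factor. Yet 16.8% of the set lay over 16-fold below its median ratio. Between testis 1 and 3, on which the set was drawn, 0.833% lay as far out. An earlier form of the test asked for 25% over 16-fold lower and found 17%, so it decided nothing. The set was chosen only against androgenic gland and ovary. Dilution with an unsampled tissue that holds part of the set therefore stays open. An androgenic gland library under a testis label is argued against by transcripts lower in androgenic gland than in both gonads, whose median log2 ratio to testis 1 and 3 was -0.0812 in testis 2 against -2.97 in androgenic gland, and an exchange of labels by the androgenic gland libraries, each of which correlated better with the other gland libraries than with testis 1 or 3, by at least 0.207 (an earlier form, on testis-high counts, was largely fixed by how that set was chosen). Androgenic gland tissue carried into the sample stays open for the gland-high part: the counts would need 25.8% of gland reads, and 5.95% of 168 abundant gland transcripts lay over 16-fold below the floor this sets, against up to 3.57% that lay as far apart between gland libraries, while 35.7% were at or below testis 1 and 3 (of the earlier forms, 1 on the level predicted with testis reads, at 23.2% over 4-fold lower against 13.7% between testis 1 and 3, decided nothing, and those that had argued against it, a log2 distance from the median to the 10th percentile of 3.69 against 1.99 and an SD of the excess of 4.46 against 1.62, were set aside because testis 1 and 3 had distances of 2.93 and 2.77 or because transcripts without an excess widened the SD). Over 4-fold below the same floor lay 19.6% of the 168 gland transcripts, against up to 8.93% as far apart between gland libraries, and carry-over still stays open. A difference between the animals or the parts of the testis sampled was not tested and stays open.

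Fewer transcripts were detected in androgenic gland than in ovary. A few abundant transcripts using up the reads could account for this, but after 402 dominant transcripts were removed and every library was thinned to 2081032 counts, 86.4% of the difference remained, with 13701 ± 261 transcripts in androgenic gland and 17349 ± 136 in ovary (SD, n = 3 each). A catalogue weighted to the female label, which 70.1% of the IDs carry, may account for the difference from ovary. Among male label transcripts the difference of ovary minus androgenic gland was -110 after the same thinning (4614.3 ± 88.5 in ovary). This cannot decide it, since male label transcripts would favour the gland if the label names male libraries. Weighting to the female label alone does not account for the difference from testis. There 5273.3 ± 133 male label transcripts were detected against 4724 ± 137 in androgenic gland. The source of the transcripts is not given, so a catalogue that favours testis over the gland stays open. A narrower set of expressed genes in the gland than in testis or ovary stays open and was not tested further.

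Same-numbered libraries of testis and androgenic gland deviated together, with correlations of 0.29 or more. This is also what would be seen if each number marked 1 male or 1 day of dissection or library preparation, and these cannot be told apart here. The correlations with other numbers are no separate support, since centring on the tissue means pulls them below 0, and the 6 ways to match the numbers are too few for a share under 0.05. The testis-high, androgenic gland-high and private transcripts are not the whole source. Without them the lowest same-number correlation was 0.30 over 14185 transcripts. Those sets had minimum levels of 10 or 20 CPM, so less abundant transcripts that set testis 2 apart can remain among the 14185.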
